A study of Mus musculus with 8 samples.

How the data were processed

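RNA from whole lung of 8 mice was measured on single-colour Agilent whole-genome arrays, with 1 array per mouse. Per the labels, 4 mice were wild type and 4 carried the Fra-2 transgene, all on the C57BL/6 background and 8 weeks old. RNA was isolated with a peqGOLD total RNA kit and labelled with Cy5 by Agilent's low-input QuickAmp procedure, per the labels' protocols. The submitters' processing notes name R 2.15.1 and limma 3.14.4. Groups and mouse numbers were taken from the labels.

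The authors deposited intensity values on a linear scale for 62976 spots on 8 arrays; the fixed plan allowed for either scale. Its steps are not given in the sources used here. The values themselves show that the arrays had been brought to a common distribution, as quantile normalization does: the median was 26.6 and the mean 1203 on each array. The lowest values lay at 0.0238 on 7 arrays and 0.182 on wild-type mouse 4, so background had been taken off, by a method that stays unknown. The highest values reached the top of the scanner's scale, 16 on the log2 scale. No flags for saturation or for spots near background were used here. A median over all spots, 4.74 on the log2 scale, served as the floor for dim signals, and this floor was chosen after the values were seen. Where a group's mean lay under the floor, the fold is a bound: the bright group's mean against the dim group's mean with each array raised to the floor, written as "at least". The same was done for Krt14 and Klri2, where 2 of 4 values of a group lay under the floor. A log2 difference printed beside such a bound is the fitted value.

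Gene names came from the platform annotation, in which 31465 spots had 1 gene symbol, none had several and 31511 were unnamed here. Symbols were updated through unversioned RefSeq accessions to the GRCm38.p6 gene names, which matched 29050 spots and replaced 2933 symbols. This gave 20863 genes, 6086 of them with more than 1 spot. The spot with the highest mean over all 8 arrays stood for each gene. Repeat spots of the same probe could not be recognised from the spot numbers, so they were not averaged.

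The log2 of each intensity, with no offset, was fitted by limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes, with 0.05 as the threshold. Changes are transgenic minus wild type, with the moderated standard error (SE). Gene lists were tested with camera at its preset correlation of 0.01, and again with an estimated correlation and with fry. Values were read with the data.table package (version 1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

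Before the data were examined, the groups, the test, the thresholds, 38 gene lists, the alternatives and the rule for named genes were fixed. The rule took Fosl2, Mep1a and Mep1b whatever their values, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, and up to 4 members with the smallest p from each list described. Which lists to describe was settled after the results were seen: those with an adjusted p under 0.05 in camera or in fry's test for change in either direction, 15 of the 37 with at least 5 measured genes. Fibrosis and vascular lists are given besides, because of the mouse model.

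The gene test was tested on simulated data with the real genes' means and spreads, 4 arrays against 4 and 20863 genes, in which 50 genes were shifted at each size. It recovered 0% at a log2 shift of 0.5, 30% at 1, 70% at 2 and 94% at 4, with 7 false calls. A simulated list shifted by 0.8 was called and no other list was. Simulated genes varied independently of each other, while the estimated correlation of real lists reached 0.769 (proliferation genes). The simulation therefore does not show how often lists of correlated genes are called falsely. The alternatives were other scalings, filters on dim genes, variance models, rules for choosing spots, thresholds, a replicate block and each mouse left out in turn. After the data were seen, offsets of 16 and 32 before the log2, both arrays numbered 4 left out, and each offset joined with leaving out wild-type mouse 4 or both mice numbered 4 were added. The number of arrays limits the precision of all values.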

Results

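Lung RNA was compared between 4 wild-type mice and 4 mice carrying a Fra-2 transgene, to ask which transcripts differ at 8 weeks of age. Fra-2, the product of Fosl2, belongs to the AP-1 family of transcription factors, and mice that overexpress it are used as a model of lung fibrosis and pulmonary vascular disease. Each mouse was measured on 1 array, and expression levels are given as log2 normalised intensity. The labels name 4 animals per group, so replicates are separate mice. Correlations with the other arrays of the same group were 0.984 for wild-type mice 1 to 3 and 0.987 to 0.988 for transgenic mice 1 to 3. Wild-type mouse 4 (0.972) and transgenic mouse 4 (0.977) stood apart from their groups.

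Fosl2, the targeted gene, was read by 2 spots that went in opposite directions. The brighter spot had log2 levels of 10.64, 10.12, 10.68 and 11.01 in wild-type mice 1 to 4 and of 10.03, 9.42, 9.38 and 10.62 in transgenic mice 1 to 4. Its group means were 10.61 ± 0.37 and 9.86 ± 0.59 (SD, n = 4 each), a log2 difference of -0.75 (SE 0.31) that did not pass the test (limma adjusted p = 0.519 over all genes; exact permutation p = 0.0571, two-sided). The dimmer spot had levels of 3.44, 4.41, 4.65 and 5.58 in wild-type mice and of 6.35, 6.98, 6.68 and 7.85 in transgenic mice. All 4 transgenic values lay above all 4 wild-type values, 4.52 ± 0.88 against 6.97 ± 0.64 (SD, n = 4 each), at least 4.06-fold, with the wild-type mean and 3 of the 4 wild-type values under the floor for dim signals. Its exact permutation p was 0.0286, two-sided, the smallest that 4 against 4 allows, and its limma p adjusted over all named spots was 0.153. Which part of the transcript each spot reads is not known here, so neither spot alone checks the genotype labels.

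**Figure D1:**
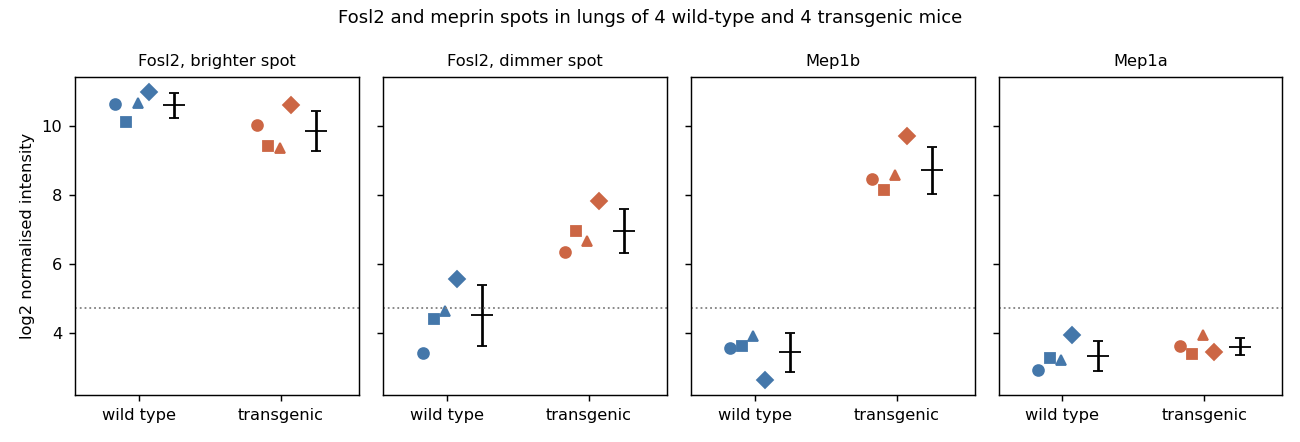
Log2 normalised intensity of the 2 Fosl2 spots and of Mep1b and Mep1a, with 1 symbol per mouse (circle, square, triangle and diamond for mice 1 to 4) and the group mean ± SD in black. The dotted line marks the floor at 4.74; the dimmer Fosl2 spot and Mep1b were higher in all 4 transgenic mice, and Mep1a lay under the floor in all 8.

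Mep1b, which encodes the beta subunit of the metalloprotease meprin, showed the largest rise among genes past the threshold. It went from 3.44 ± 0.56 in wild-type lung to 8.73 ± 0.68 in transgenic lung (SD, n = 4 each), at least 15.9-fold (log2 difference 5.28, SE 0.39, limma adjusted p = 0.00446). Mep1a, which encodes the alpha subunit, lay under the floor in both groups (3.34 and 3.61, adjusted p = 0.780). Mucl1, a mucin-like gene, rose at least 13-fold, Rnf183, a ubiquitin ligase, at least 10.6-fold (log2 difference 3.80, SE 0.24, limma adjusted p = 0.00182), Clrn1 at least 3.81-fold and Cd109, a membrane-anchored protein, at least 3.19-fold. In these 4 the wild-type mean lay under the floor. Krt14, a keratin of basal epithelial cells, rose at least 6.44-fold, with 2 of 4 wild-type values under the floor. Among genes above the floor in all 8 mice, Upp1, the uridine phosphorylase, rose 7.14-fold (2.83, SE 0.24) and Prss12, a serine protease, 4.86-fold (2.28, SE 0.21). Pkn3, a protein kinase, rose 3.86-fold, Akr1b8, an aldo-keto reductase, 3.19-fold, Cd34, a surface protein of endothelial and progenitor cells, 3.18-fold from 13.31 ± 0.31 to 14.98 ± 0.17 (SD, n = 4 each), and Fam181b 3.10-fold. The adjusted p-values of these 12 rises ran from 0.00182 (Rnf183) to 0.0181 (Mucl1). The bounds rest on the floor chosen: an offset of 32 with both mice numbered 4 left out, where offsets shrink dim changes, brought the fitted log2 difference to 3.03 for Mep1b, 2.78 for Mucl1, 2.56 for Rnf183, 1.55 for Clrn1, 1.06 for Cd109 and 1.77 for Krt14. With any 1 mouse left out Mep1b, Rnf183, Clrn1, Upp1, Prss12 and Pkn3 still passed. Calls were lost for Mucl1 when any 1 wild-type mouse or transgenic mouse 4 was left out (adjusted p from 0.0613 to 0.0873), Cd34 without wild-type mouse 1, 2 or 3 or transgenic mouse 2 or 3 (0.0501 to 0.0613), Akr1b8 without wild-type mouse 1, 2 or 3 or transgenic mouse 3 (0.0504 to 0.0582), Fam181b without wild-type mouse 2 or 3 (0.05001 and 0.0552), Cd109 without wild-type mouse 2 or transgenic mouse 3 (0.0503 and 0.0521) and Krt14 without wild-type mouse 2 (0.05001).

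The genes that fell were led by natural killer cell genes. Gzma, a protease of cytotoxic granules, had levels of 12.52 to 13.49 in the 4 wild-type mice and of 8.26 to 9.79 in the 4 transgenic mice, a 15.7-fold fall (log2 difference -3.97, SE 0.36, limma adjusted p = 0.00709). Klra8, a receptor of natural killer cells, went from 9.34 ± 0.34 to 5.52 ± 0.24, a 14.2-fold fall (-3.83, SE 0.20, limma adjusted p = 0.000888). Klre1 fell at least 6.37-fold and Klrb1 at least 3.32-fold, with the transgenic mean under the floor. Klra4 fell 7.19-fold, Klra22 6.15-fold, Klrb1a 6.00-fold, Klra7 5.65-fold, Klra16 5.20-fold and Klra23 4.61-fold, and Klri2 at least 4.56-fold with 2 of 4 transgenic values under the floor. Esm1, a proteoglycan made by endothelial cells, fell 4.64-fold (-2.21, SE 0.29, limma adjusted p = 0.0303). Of the 29 genes with a Klr receptor symbol, 12 fell, 0 rose and 29 had a negative difference, with a median of -1.53; these 12 made up more of the 19 falling genes than chance allows (Fisher's exact test, two-sided p = 1.84e-31, on a family chosen after its values were seen and on genes that are not independent). With 1 mouse left out, 26 (without wild-type mouse 4) to 29 of the 29 differences were negative. The 3 other scalings left the values as they were, because the arrays already shared 1 distribution, so they test nothing here. Offsets of 16 and 32 brought the median to -1.06 and -1.01. With the offset of 32 it was -0.84 without both mice numbered 4 and -0.71 without wild-type mouse 4. The 12 became 7 without wild-type mouse 2 or transgenic mouse 3, 8 without wild-type mouse 3 and 5 without both mice numbered 4. With the offset of 32 and, for Klrb1, wild-type mouse 4 left out, the fitted log2 difference was -1.93 for Klre1, -1.24 for Klrb1 and -1.44 for Klri2. With the mean of all spots of a gene it was -1.51 for Klra7 and -1.39 for Klra16. The weakest fitted difference over all alternatives was -3.01 for Klra8 and -1.76 for Klra22. Klra genes are near copies of each other, so a spot may read several of them. The level of a single member is therefore uncertain, as is whether each named Klra gene fell. Counts of Klr genes carry the same limit. With any 1 mouse left out Gzma, Klra8, Klre1, Klra4, Klra22, Klrb1a, Klra7 and Klra16 still passed. Calls were lost for Esm1 when any 1 mouse other than transgenic mouse 2 was left out (adjusted p from 0.0521 to 0.134), Klrb1 (0.0579 to 0.0694) and Klra23 (0.05001 to 0.0554) without wild-type mouse 2 or 3 or transgenic mouse 3, and Klri2 without wild-type mouse 2 or transgenic mouse 3 (0.05001 and 0.0521).

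Over all genes, 45 of 20863 passed the threshold, 26 higher and 19 lower in transgenic lung, and their groups did not overlap in any of the 45. A change of at least 2-fold was seen in 38 of them, 19 higher and 19 lower. Gje1, which also passed, lay under the floor in both groups (2.02 and 3.51), so no fold is given for it. Values without overlap between the groups were found for 1362 genes (832 higher, 530 lower), 6.53% of those tested, where chance gives 2.86%. The count of 45 became 27 (11 higher, 16 lower), 17 (7 and 10) and 20 (8 and 12) without wild-type mouse 1, 2 or 3. It became 29 (15 and 14), 27 (12 and 15) and 20 (10 and 10) without transgenic mouse 1, 2 or 3. The excess of higher over lower genes was turned or lost in 5 of these 6 fits. Without wild-type mouse 4 the count was 35 (20 and 15), with the excess kept. Without transgenic mouse 4 it was 38 (19 and 19), with the excess lost. Without both mice numbered 4 the count became 17, of which 14 were among the 45. Among called genes, 11 had at least 2 spots above the floor, and in all 11 these spots went the same way, as they did in 2611 of the 4009 genes with such spots overall.

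**Figure D2:**
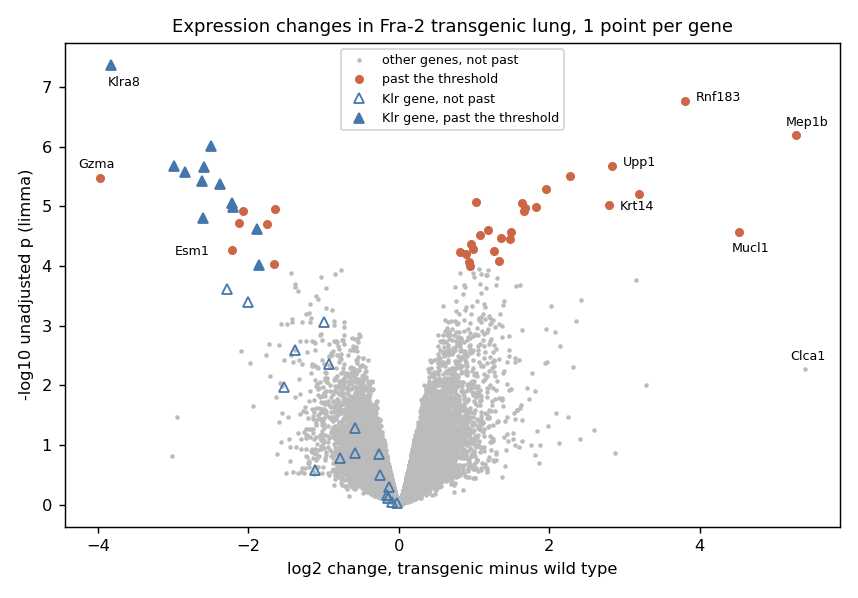
Log2 change (transgenic minus wild type, n = 4 each) against -log10 of the unadjusted limma p for 20863 genes, with 1 point per gene. Filled symbols mark the 45 genes past the threshold and triangles the 29 Klr genes, all of which lie to the left of 0.

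T and NK cell genes split in both directions. Of 21 measured, 0 rose and 2 fell over all genes (Gzma and Ncr1; 9 higher and 5 lower at an unadjusted limma p under 0.05), and adjusted over the list alone 8 were higher, 5 lower and 8 not past; fry's test for change in either direction gave an adjusted p of 5.45e-06. Ncr1, an activating receptor of natural killer cells, fell at least 2.77-fold (log2 difference -2.12, SE 0.24, limma adjusted p = 0.0150); its call was lost without wild-type mouse 2, 3 or 4 or transgenic mouse 1 or 4 (adjusted p from 0.0521 to 0.0724), and its fitted difference was -1.11 with an offset of 32. Past the list's own threshold and lower were also Klrb1c (-2.01), Gzmb (-1.57) and Nkg7 (-0.93), which like Cd28, Cd3d and Lat were picked as examples after their values were seen. Higher were the T cell genes Cd5 (1.40, SE 0.24), Cd28 (1.37, SE 0.28), Cd3d (1.26, SE 0.30), Lat (1.15, SE 0.21) and Tcf7 (0.85, SE 0.14); none of these passed over all genes (limma adjusted p from 0.0846 for Tcf7 to 0.219 for Cd3d). Camera, which asks for 1 common direction, did not call the list over all 8 mice (adjusted p = 0.0912). It called the list higher without wild-type mouse 2 (0.0207, and adjusted p = 0.852 with an estimated correlation) or transgenic mouse 3 (0.0453, and adjusted p = 0.945 with an estimated correlation). Thymus and lymph node genes, listed as a mark of tissue carried over with the lung, were higher in the same samples (median 0.37, camera adjusted p = 0.0184, and adjusted p = 0.804 with an estimated correlation).

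**Figure D3:**
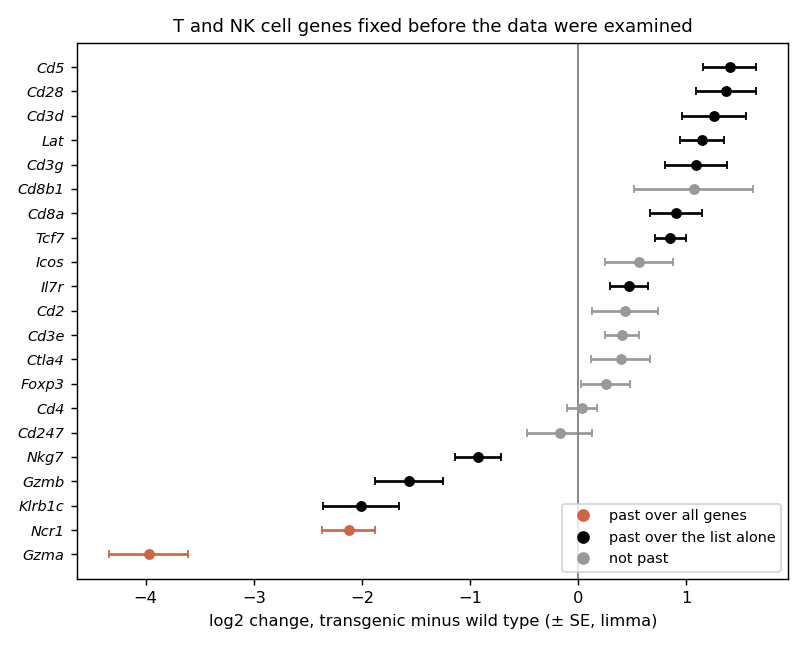
Log2 change (transgenic minus wild type) with its SE from limma for the 21 measured T and NK cell genes. Gzma and Ncr1 passed over all genes, black points passed when adjusted over the list alone, and the T cell genes Cd5, Cd28 and Cd3d lie at the positive end.

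In 7 other lists, of cell types, chemokines, matrix proteases and hypoxia, at most 1 gene each passed over all genes, and camera called none of the 7 over all 8 mice. Marco, a scavenger receptor of alveolar macrophages, fell 4.22-fold (-2.08, SE 0.22, limma adjusted p = 0.0105), while the other 15 measured alveolar macrophage genes did not pass, over all genes or adjusted over the list alone. Its call was lost without transgenic mouse 1 or 2 (adjusted p = 0.0525 each). In the list for capillary and arterial endothelium, 0 of 14 passed over all genes (limma; 4 at an unadjusted p under 0.05), and adjusted over the list alone 2 were higher and 2 lower: Aplnr, the apelin receptor, differed by 1.56 (SE 0.25) and Cxcl12 by 1.12 (SE 0.25), against -1.03 (SE 0.22) for Apln, the apelin ligand, and -1.23 (SE 0.23) for Fibin. Of 17 pan-endothelial genes 0 passed over all genes (3 at an unadjusted p under 0.05), and adjusted over the list alone 1 was higher, Sox17 (0.87, SE 0.14, limma adjusted p = 0.0702 over all genes). Camera gave the pan-endothelial list an adjusted p of 0.168 over all 8 mice. It called the list higher without transgenic mouse 4 (median 0.16, adjusted p = 0.0177, and adjusted p = 0.761 with an estimated correlation). The same held without both mice numbered 4 (median 0.16, adjusted p = 0.0119, and adjusted p = 0.780 with an estimated correlation). Of 14 keratinocyte genes Krt14 rose, and adjusted over the list alone Krt15 (0.75, SE 0.15) was higher too and Sprr1a lower, at least 1.90-fold, with the transgenic mean under the floor. Trp63 of that list differed by -0.52 (SE 0.17) and passed neither way (limma adjusted p = 0.425 over all genes). Of 26 chemokines and cytokines 0 passed over all genes (5 at an unadjusted p under 0.05), and adjusted over the list alone 2 were higher, Ccl9 (2.02, SE 0.36) and Csf2 (0.99, SE 0.23), and 3 lower, Ccl5 (-1.49, SE 0.30), Ccl4 (-1.76, SE 0.43) and Cxcl16 (-0.48, SE 0.12), the last named after its values were seen. Of 25 matrix proteases and inhibitors Mep1b alone passed, over all genes and adjusted over the list alone; Mmp12, which did not pass (limma adjusted p = 0.516), stood at 7.40 in transgenic mouse 4 and at 4.49 to 5.29 in the other 3, with all 4 wild-type values under the floor. Of 18 hypoxia genes 0 passed either way (4 at an unadjusted p under 0.05); P4ha2 differed by -0.56 and Car9 by 0.69. Fry's adjusted p for change in either direction ran from 9.96e-05 for capillary and arterial endothelium to 0.0390 for hypoxia.

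Camera called none of the fibrosis and vascular lists over all 8 mice. Of 16 lung fibroblast genes 0 passed over all genes and 0 adjusted over the list alone (limma; 2 at an unadjusted p under 0.05), and 12 had negative differences (median -0.25, camera adjusted p = 0.0842). That list was called lower without wild-type mouse 2 (adjusted p = 0.0248), transgenic mouse 2 (0.0117) or transgenic mouse 3 (0.0453), though not with an estimated correlation (adjusted p = 0.852, 0.855 and 0.940). Of 15 collagen genes 0 passed over all genes and 0 adjusted over the list alone (limma; 4 higher and 1 lower at an unadjusted p under 0.05; camera adjusted p = 0.168). Col1a1 differed by 0.52 (SE 0.18), Col4a1 by 0.73 (SE 0.24) and Col12a1 by -0.75 (SE 0.24). Of 21 matricellular and fibrosis genes 0 passed either way (1 at an unadjusted p under 0.05; camera adjusted p = 0.921), with Fbln1 at -0.50 (SE 0.20) and Ccn2 at -0.39 (SE 0.18). Of 18 TGF-beta response genes 0 passed either way (1 at an unadjusted p under 0.05; camera adjusted p = 0.879), with Inhba at 1.00 (SE 0.30). Of 26 genes of pulmonary vascular tone and BMP signalling 0 passed over all genes (5 at an unadjusted p under 0.05) and 1 was higher adjusted over the list alone: Nos3, the endothelial nitric oxide synthase, differed by 0.76 (SE 0.14), and Bmpr2 by -0.65 (SE 0.17). These tests do not exclude small shifts, nor shifts of 1 on the log2 scale in single genes. On simulated data the gene test recovered 0% at a log2 shift of 0.5 and 30% at 1.

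Camera called 7 of 37 lists, 5 lower and 2 higher in transgenic lung. Of the 35 splits of the mice into 4 and 4, 26 gave as many, the real one included. The highest other split gave 17. The number of calls therefore does not argue against chance, and the directions below describe these mice. With the real groups, the count was 11 without wild-type mouse 2 and 11 without transgenic mouse 3. Without both mice numbered 4 it was 7. Of these, 3 (immediate early, AP-1 and smooth muscle) were among the 7 called with all mice kept. The other 4 were pan-endothelial, red cell, MHC class I and neutrophil genes. Immediate early genes were lower (median -0.52; camera adjusted p = 2.79e-05, and adjusted p = 0.804 with an estimated correlation): 16 of 18 had negative differences, among them Nr4a1 (-1.12, SE 0.32), Btg2 (-0.76, SE 0.22) and Dnajb1 (-0.97, SE 0.36). AP-1 genes were lower (median -0.38; adjusted p = 0.000109, and adjusted p = 0.804 with an estimated correlation), with 11 of 14 negative, among them Atf3 (-1.71, SE 0.48), Fosb (-1.33, SE 0.38), Fos (-0.86, SE 0.32) and the brighter spot of Fosl2. Smooth muscle contractile genes were lower (median -0.31; adjusted p = 0.000109, and adjusted p = 0.804 with an estimated correlation), with 14 of 14 negative, among them Mylk (-0.53, SE 0.14), Cnn1 (-0.48, SE 0.17) and Tagln (-0.31, SE 0.13). Ciliated cell genes had a median of -0.30 (adjusted p = 0.00397, and adjusted p = 0.942 with an estimated correlation), with Tppp3 at -0.37 (SE 0.15) and Foxj1 at -0.29 (SE 0.17); the call was lost without wild-type mouse 4 (adjusted p = 0.363, median -0.10). Cardiac and striated muscle genes had a median of -0.30 (adjusted p = 0.0402, and adjusted p = 0.942 with an estimated correlation), with Nppa at -1.63 (SE 0.54) and Myh7 at -0.97 (SE 0.37). That call was lost without wild-type mouse 1 (adjusted p = 0.438), wild-type mouse 3 (0.0760) or transgenic mouse 4 (0.782, median 0.14). Thymus and lymph node genes were higher (median 0.37; adjusted p = 0.0184, and adjusted p = 0.804 with an estimated correlation), with Dntt at 1.24 (SE 0.24, 1 of 4 wild-type values under the floor) and Themis at least 1.09-fold higher with the wild-type mean under the floor, though at -0.45 on its most variable spot; the call was lost without wild-type mouse 4 (adjusted p = 0.109) and with the most variable spot of each gene (0.115). No member of these 7 lists passed over all genes (limma; 1 to 7 members of each at an unadjusted p under 0.05), and adjusted over the list alone only Dntt and Themis did. Fry's directional test called 0 of 37 lists and camera with an estimated correlation 0, with 6 and 2 lists at an unadjusted p under 0.05.

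Type 2 response genes, the seventh list called, were higher (median 0.91; camera adjusted p = 0.000383, and adjusted p = 0.942 with an estimated correlation), and 19 of 20 had positive differences. Of the 20, 0 passed over all genes and 0 adjusted over the list alone (limma; 3 at an unadjusted p under 0.05). Clca1, a goblet cell gene, differed by 5.40 (SE 1.44) with transgenic mouse 4 at 16, the top of the scale, so that its true level there is open. Ccl8 differed by 2.59 (SE 1.17), Itln1 by 1.81 (SE 0.57) and Ccl11 by 1.31 (SE 0.54). Transgenic mouse 4 stood far above the others for some of these genes. Ccl8 stood at 13.96 in that mouse and at 9.06 in the next highest transgenic mouse, and Ccl24 at 10.06 and 6.02. Between the other 3 transgenic mice and the wild-type mice, the mean difference was 4.23 for Clca1 and 2.07 for Itln1, against 1.25 for Ccl8 and 0.67 for Ccl24. Wild-type mouse 4 stood at 10.10 for Clca1, above transgenic mouse 1 (9.51), and at 9.71 for Itln1, above transgenic mouse 4 (9.57). Without wild-type mouse 4 these differences became 5.23 for Clca1 and 2.45 for Itln1, and that of Clca1 over all 4 transgenic mice became 6.40. Without transgenic mouse 4 the median was 0.36 (adjusted p = 0.0362, and adjusted p = 0.649 with an estimated correlation), and without both mice numbered 4 it was 0.22 and the call was lost (adjusted p = 0.188).

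**Figure D4:**
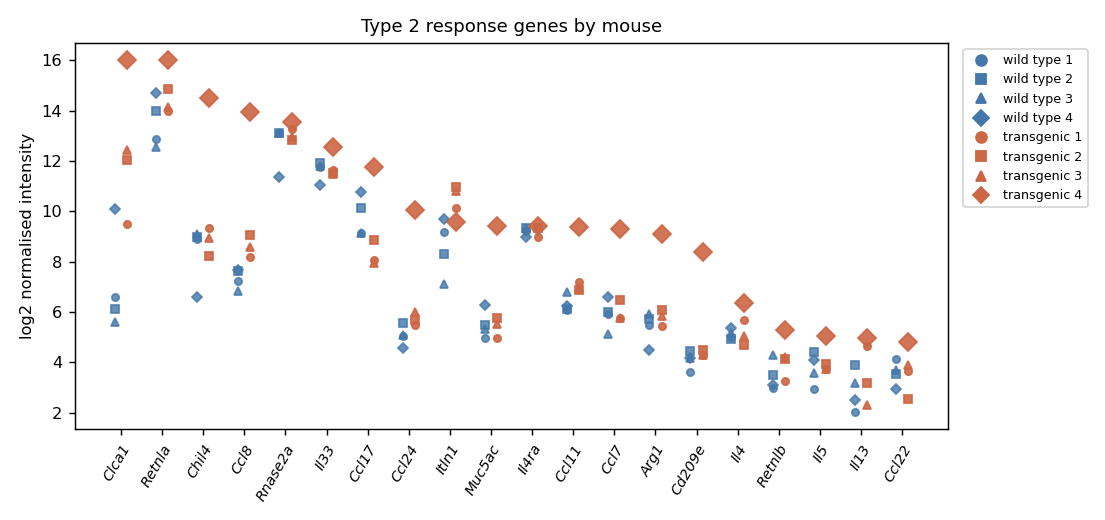
Log2 normalised intensity of the 20 measured type 2 response genes, with wild-type mice in blue and transgenic mice in orange and a symbol for each mouse number. The large orange diamonds, transgenic mouse 4, stand above the other 7 mice for genes such as Ccl8 (13.96) and Ccl24 (10.06).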

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

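The tests of transgenic mouse 4 in this part were chosen after its values had been seen, apart from those of the further spots below. A sample was picked out where its gap to the nearest mouse of its group was large against the group's whole range. Among the 82 genes named by rule, in 2 groups of 4 mice each, 15 of 164 groups had such a sample, where chance gives about 1 in 20, or 8.2; it was transgenic mouse 4 in 6 and wild-type mouse 4 in 4. Another 16 type 2 response genes were scanned because transgenic mouse 4 had been seen to stand apart in that list, so their 7 further samples do not count as evidence that it does.

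In transgenic mouse 4 the gap's share of the range was 0.945 for Cd209e (8.38 against 4.51 in the next mouse), 0.887 for Ccl24, 0.871 for Ccl11 (9.39 against 7.20), 0.861 for Il33, and 0.846 for Ccl8 and Il5, all on the high side. It was high as well for P4ha1 (0.902) and Fos (0.847), and low for Nppa (0.862, 7.35 against 9.21) and Mb (0.846). In wild-type mouse 4 the shares were 0.980 for Rnase2a (11.38 against 13.09), 0.916 for Chil4 (6.59 against 8.88), 0.889 for Esm1 and 0.830 for Cxcl12 on the low side, and 0.911 for Tekt4 and 0.842 for P4ha2 on the high side. The other 6 were Dnajb1 in transgenic mouse 2 (0.944, in a group that spans little), Bnip3 in wild-type mouse 3 (0.905), Tekt4 in transgenic mouse 1 (0.860), Marco in wild-type mouse 2 (0.854), Il4ra in transgenic mouse 1 (0.849) and Emcn in transgenic mouse 3 (0.847).

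Type 2 response genes in transgenic mouse 4 form the pattern weighed here. In that mouse 19 of the 20 list genes lay above the mean of the other 3 transgenic mice, with Chil4 50.4-fold and Ccl8 41-fold higher and Itln1 the exception. Noise of that array stays open, as the list was looked at because the mouse stood out in it. The 12 further spots of its genes, not used for the list, had a median difference of 0.86 (SE 0.51). They came from 3 genes, with Il4 and Il4ra higher and Itln1 lower, each the same way as the gene's spot in the list. Most read Il4 near the floor (means of 4.74 to 5.13), so the SE counts spots of 1 gene in 1 mouse as separate. A wild-type sample under a transgenic label is argued against, since Mep1b in that mouse lay at least 4.97 above every wild-type mouse on the log2 scale, counted from the floor. A type 2 airway response in this mouse may stand behind the pattern, from an infection, an allergen or the genotype, and these data cannot separate them because it is 1 mouse.

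Spots without a gene name were left out of the comparisons. When all 62976 spots were tested singly with limma, 6 unnamed spots passed, 1 higher and 5 lower in transgenic lung, beside 41 named ones.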

How the results depend on the processing

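Alternatives with an offset of 16 or 32, or without both mice numbered 4, were chosen after seeing the data. The 45 genes became 77 with the dimmest genes left out (13909 tested), 118 with an intensity trend and robust variances, 100 with array weights and 4 with no variance moderation; 14 passed an adjusted p of 0.01 and 76 one of 0.10. They became 80 and 88 with offsets of 16 and 32, 17 without both mice numbered 4, and 17 to 38 with 1 mouse left out. Joined with an offset of 16 or 32, leaving out wild-type mouse 4 gave 76 and 111, and leaving out both mice numbered 4 gave 110 and 200, of which 42 and 43 were among the 45. With a replicate block 5 genes passed (2 higher, 3 lower), 3 of them Klr genes, of which 1 passed with no variance moderation. The numbers were not taken as pairs because the labels do not say that they pair animals. Same-numbered mice had deviations correlated at 0.14, -0.01, 0.15 and 0.07, and 0.15 and 0.14 were the highest of all pairings. Every mouse but wild-type mouse 2 and transgenic mouse 2 correlated best with its own number, so a batch shared by number stays open. Other scalings left the 45 as they were, as the values were already normalised. Rnf183 and Klra8 kept their calls in all 26 and 27 alternatives, while Mep1b lost its call in 2 (adjusted p from 4.94e-05 to 0.103) and Esm1 in 11. The other scalings, counted among these alternatives, could change little. Lists called were 0 with an estimated correlation, 0 with fry and 6 to 11 with 1 mouse left out. With all 8 mice kept they were 9 with an offset of 16 or 32, of which 7 were among the 7. They were 9 with the most variable spot (6 among the 7), 8 with the dimmest genes left out (7 among the 7) and 8 with the dimmer genes left out (6 among the 7). Genes without overlap were 853 with the dimmer genes left out (10432 tested), 3687 without both mice numbered 4, 3682 with either offset as well, and 2449 and 2450 without wild-type mouse 4 under the offsets of 16 and 32; fewer mice per group make gaps by chance more common. Fosl2 reversed to 0.85 with the mean of its spots and 2.45 with its most variable spot, as its 2 spots disagree. Trp63 reversed to 0.49 and Themis to -0.45 with the most variable spot; the cause was not tested, nor was it for the changed counts. Near background, where no detection flags were used here, folds are bounds.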

Other observations

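The tests of T cell genes, red cell genes, the Fosl2 spots and symbol families in this part, the examples among the other called genes, and the further lists called with mice left out, were chosen after their results were seen. Natural killer genes outside the Klr cluster and the counts over other splits were set before theirs. Outside the 24 largest changes, 21 more genes passed the threshold, 14 higher and 7 lower in transgenic lung. Higher were Abcb4, a phospholipid transporter, 2.79-fold (log2 difference 1.48, SE 0.18, limma adjusted p = 0.0215), Dysf, a membrane repair protein, 2.40-fold (1.26, SE 0.17), Cavin3, a protein of caveolae, 2.28-fold (1.19, SE 0.14), Ass1, an enzyme of arginine synthesis, 1.92-fold and Itgb4, an epithelial integrin, 1.91-fold. Lower were Xpnpep2, an aminopeptidase, 3.37-fold, Adamts14, a matrix protease, 3.15-fold and Gal, the precursor of galanin, by -1.65 on the log2 scale (SE 0.18, limma adjusted p = 0.0105). With each of the 8 mice left out in turn, Gal passed in 7 of 8 fits, Cavin3 and Xpnpep2 in 2, Abcb4, Dysf, Itgb4 and Adamts14 in 1, and Ass1 in 0 (adjusted p from 0.0798 to 0.184).

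Natural killer genes outside the Klr cluster had mostly negative differences. Of 15 measured, 12 had negative differences with a median of -0.65, 6 were lower without overlap and 0 higher. Eomes (-1.38, SE 0.22), Tbx21 (-1.41, SE 0.36), Fasl (-1.29, SE 0.25), Prf1 (-1.07, SE 0.33), Ctsw (-0.89, SE 0.22) and S1pr5 (-0.84, SE 0.26) passed when adjusted over the list alone, and 0 passed over all genes (limma; 7 at an unadjusted p under 0.05). The seventh, Itga2, was positive (0.62, SE 0.23). In a scan of 478 gene families by symbol, 2 passed camera, and Klr had the smaller p (adjusted p = 1.95e-30, and adjusted p = 0.997 with an estimated correlation).

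Red cell genes were not called over all 8 mice (median -0.19, camera adjusted p = 0.0560). They were called lower without transgenic mouse 4 (median -0.48, adjusted p = 2.04e-05, and adjusted p = 0.649 with an estimated correlation). Without both mice numbered 4 the median was -0.50 (adjusted p = 2.10e-05, and adjusted p = 0.702 with an estimated correlation). Without wild-type mouse 4 it was -0.29 (adjusted p = 0.0333, and adjusted p = 0.891 with an estimated correlation). Of 9 measured members 7 had negative differences, and most of the list was dim or near the top of the scale. Hbb-bs differed by -1.38 (SE 0.45), Alas2 by -1.28 (SE 0.48), Hbb-b2 by -1.04 (SE 0.39) and Slc4a1 by 0.16 (SE 0.57). None of the 4 passed, over all genes or adjusted over the list alone.

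Further lists were called in fits with mice left out. MHC class I genes, not called over all 8 mice (median -0.17, camera adjusted p = 0.162), were lower without wild-type mouse 4 (-0.24, adjusted p = 0.00353), transgenic mouse 4 (-0.15, 0.0260) and both (-0.34, 1.76e-05). Neutrophil genes, not called over all 8 mice (median -0.12, adjusted p = 0.290), were lower without wild-type mouse 4 (-0.37, adjusted p = 0.0201) and without both mice numbered 4 (adjusted p = 0.00206). B and plasma cell genes were higher without wild-type mouse 2 (0.0376) or transgenic mouse 3 (0.0188), and proliferation genes without wild-type mouse 2 (0.0128) or transgenic mouse 1 (0.00104). Alveolar type 1 genes were lower without wild-type mouse 4 (0.0356) or transgenic mouse 3 (0.0116), and cholesterol and fatty acid synthesis genes without wild-type mouse 4 (0.0333). None of these calls held with an estimated correlation (adjusted p from 0.780 to 0.940).

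The fall of Klr genes and Gzma is the next pattern weighed. A different allele of the Klr cluster, or probes that read several Klr genes, is argued against as the whole cause by the median of -0.65 in genes outside the cluster, 0 of which lie on its chromosome; the larger Klr changes may still hold a part of it. Fewer lymphocytes of every kind in the samples as taken are argued against by the 16 T cell genes of the T and NK list. Their median difference was 0.71, with 15 of 16 positive (Cd247 at -0.17). Genes of this list vary together (estimated correlation 0.476), and 0 of them rose over all genes. The median of the whole list was 0.43 over all 8 mice and 0.21 without both mice numbered 4. Lymphoid tissue carried over with some lungs could also add T cells (thymus and lymph node genes had a median of 0.37), so fewer T cells in the lung itself stays open. Less blood in the transgenic lungs stays open too, as the red cell list had a median of -0.19 over all 8 mice and of -0.48 without transgenic mouse 4. Of its 9 measured members 7 were negative and 2 positive, and most of the 9 were dim or near the top of the scale. A smaller number of natural killer cells in transgenic lung, or a lower expression in them, is a hypothesis that whole-lung values cannot divide further.

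Opposite values of the Fosl2 spots are the last pattern weighed. A transgene transcript read by the dimmer spot only may explain them, but the gap of 0.78 on the log2 scale between that spot's lowest transgenic and highest wild-type mouse is the pattern itself and tests nothing, so this stays open without the probe sequences. Less stress at dissection in the transgenic samples, where immediate early genes were lower, could lower the brighter spot; with the mean of those genes as a covariate its difference was -0.24 (SE 0.48), too wide to decide, so this cannot be told apart from a lower endogenous transcript.

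Chance as the source of the 45 genes was tested over all 35 splits of the 8 mice into 4 and 4. The real split alone gave as many (1 of 35), and the highest other gave 0. This argues against chance, but 1 of 35 is the smallest share that 4 against 4 allows, so chance cannot be excluded. Every other split mixes wild-type and transgenic mice, so a real difference would add to its spread and lower its count. For genes without overlap the real split gave 1362 and the highest other 839. Again 1 of 35 gave as many, with the same limit. For the lists the splits did not argue against chance: the real split gave 7, 26 of 35 splits gave as many, and the highest other gave 17.

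Sex is not given in the labels. Of 5 sex-linked genes 4 were measured, too few for a list test; Xist lay between 6.65 and 7.48 in all 8 mice and Eif2s3y between 5.54 and 6.81, and no mouse stood apart.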
